A study of Streptococcus thermophilus with 3 samples.

How the data were processed

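Total RNA of treated and untreated LMD-9 cultures was copied to cDNA, labelled with Alexa Fluor 555 and 647 and hybridised to 3 arrays of one custom Agilent slide (1 slide, 1 scan day), per the labels' protocols and the file headers. The deposited files hold spot intensity values (mean signal and median local background, not normalized, and processed signals that were background-subtracted, detrended and dye-normalized by linear and LOWESS steps) made with Agilent Feature Extraction 9.1, per the file headers. The deposited log10 ratio of red over green processed signal stands beside them. The authors' series table held the same log10 ratio on every spot (largest difference 0) and was not turned for the dye swap; its column medians were 0, 0.0009 and -0.0035. The genome build behind the probes is not given in the sources used here.

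Each array had 15744 spots, of which 536 were controls. Of the 8410 probes 6798 were spotted 2 times, and 1448 of the 1923 tags had 5 probes. Median green and red signals were 924.6 and 5011.6 on array 1, 1096.7 and 4048.9 on array 2, and 1822.5 and 1076.3 on array 3, before normalization. The outlier spots left out numbered 47, 48 and 4. The filter on dim probes removed 0 probes.

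The mean signal was background-corrected by normexp with an offset of 50 and normalized within each array by loess, with controls and outliers at weight 0 (limma 3.58.1, R 4.3.3). The dyes in the labels gave the direction, and array 3 was turned to treated over untreated. Spots were averaged to probes and probes to genes; the median SD between probes of a gene was 0.054 (log2) over 1690 genes with at least 3 probes. Arrays 1 and 3 were averaged to 1 replicate, because they share a culture pair according to the labels, and the 2 replicates were tested against 0 with lmFit and eBayes. With 1 residual degree of freedom the test leans on the spread pooled over genes (prior SD 0.192, prior degrees of freedom 15.9). The median SD between the culture pairs was 0.13. Array 2 had no dye swap, so the dye effect of culture pair 2 is not removed.

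On 20 simulated data sets with 200 of 1923 genes changed, the fit for this comparison recovered 99.7% of the genes changed 2-fold and 100% of those changed 4-fold. There, 4.9% of calls were of genes not changed, and 0.4 genes on average were called when none was changed. Camera called a raised list in 100% of sets and an unchanged list in 0%. The simulated genes were independent and carried no dye or position effect. Arrays 1 and 3 were simulated with a smaller spread between them than between culture pairs, yet in the data they correlated least (0.6). The simulated rates therefore need not hold for these data.

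The comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from the changes and additions named below. The rule took the 12 highest and 12 lowest genes that passed and had one sign on 3 arrays, members of 25 lists chosen by gene symbol or product, and a set of DNA repair and competence genes. The files pair no tag with a symbol or product, so the lists and that set could not be matched and no list was tested. Of the 24 genes, the 2 printed per direction are the most extreme one and the most extreme one outside its run, a choice made after their values were seen. Groups by tag letter and by the hydropathy of translated probes took the place of the lists, also after the files were seen. A gene counted as hydrophobic when it had at least 3 scored probes and one translated probe, of at most 20 residues, with a mean Kyte-Doolittle value of at least 1.6. This covered 1674 tags. Frames were chosen by codon use, and 99.4% of probes of numbered tags had an open forward frame against 76.5% in reverse. Camera was run with a preset correlation of 0.01 over 4 groups. The 1 tag with the letter s was in no group.

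Tag order served for runs and for distance. The search for runs, with its shuffles and the correlation of adjacent tags, was not part of the plan fixed beforehand. The planned test by 10000 circular shifts has 1875 distinct shifts, all of which were used, and it asks mostly whether a trend is centred on tag 1; shuffled blocks of 50 tags were added. Alternatives covered background correction, normalization, probe filters, probe averaging, the handling of the 3 arrays and the set tests. Where each probe was tested by itself, a printed gene was given by its most extreme probe, so its call there rests on that probe. The least extreme probes had log2 ratios of 1.95 for STER_0077, 1.98 for STER_0919, -3.7 for STER_1840 and -2.7 for STER_0189. Apart from that of STER_0919, these lie outside the ranges given below for the alternatives. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.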

Results

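Gene expression was measured in Streptococcus thermophilus LMD-9, a lactic acid bacterium used in milk fermentation, with and without mitomycin C, a drug that cross-links DNA. The labels state a dose of 0.08 µg/ml, growth at 37 °C for 16 h in M17 broth with 1% lactose, a 30-fold dilution into a chemically defined medium with lactose, and harvest at an optical density of 0.4. They do not settle whether the drug was present in the first culture, the second or both. RNA from treated and untreated cultures was hybridised together on 3 two-colour arrays. Arrays 1 and 2 each held a different pair of cultures, with the treated RNA in Alexa Fluor 647 (red) and the untreated RNA in Alexa Fluor 555 (green). According to the labels, array 3 held the pair of array 1 with the dyes exchanged, so the comparison was treated as resting on 2 biological replicates. Each array carried 15208 gene spots of 8410 probes, 60 bases long, for 1923 locus tags. At least 99.78% of the gene spots in either channel of each array were well above background and 0 were saturated. The number of arrays limits the precision. The files name genes by locus tag only, and the tags are described here by value, by probe sequence and by their order.

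The first comparison asked which genes differ in expression between treated and untreated cells. Of 1923 genes, 503 (26.2%) changed with mitomycin C, 240 upward and 263 downward. The falls reached further than the rises: 49 genes fell and 27 rose by at least 2-fold, and 9 fell and 4 rose by at least 4-fold. Most of the 9 lay in a single run of 13 neighbouring tags, so the contrast at 4-fold rests on that run. Most changes were small, with a median of 1.48-fold among the genes that rose and 1.51-fold among those that fell. The direction was the same on all 3 arrays for 467 of the 503 genes (92.8%) and for 74 of the 76 genes that changed by at least 2-fold. The genes were called on the mean of the same arrays, so part of this agreement is built in. The counts of changed genes come from limma with Benjamini-Hochberg adjustment at 0.05, and 735 genes had an unadjusted p under 0.05. The count depends on how the arrays are combined: 264 genes passed with a dye term over the 3 arrays and 333 without array 1, while 66 and 69 genes passed with a change of at least 2-fold, of which 60 and 63 were among the 76.

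STER_1840 fell furthest, to a log2 ratio of treated over untreated of -4.03 ± 0.32 (SD, n = 2 culture pairs), or 16.3-fold lower (limma adjusted p = 1.17e-12). Its ratio was -3.79 on array 1, -3.8 on array 2 and -4.73 on array 3. The probe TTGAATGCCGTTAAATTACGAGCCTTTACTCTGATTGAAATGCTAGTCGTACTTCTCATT, with a GC content of 36.7%, gave -3.9, and the 5 probes of the gene lay between -4.48 and -3.7. STER_1840 belonged to 13 consecutive measured tags that all fell, with a mean log2 ratio of -2.25 ± 0.11 (SD, n = 2) and single values from -4.03 to -0.4. STER_0189 fell to -3.08 ± 0.22 (SD, n = 2), or 8.43-fold lower (limma adjusted p = 1.46e-11), and was not in such a run. Its probe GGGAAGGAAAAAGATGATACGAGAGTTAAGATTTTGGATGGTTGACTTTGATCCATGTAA gave -3.07. The 12 genes that fell furthest lay between -4.03 and -1.8, and 9 of them were in 3 runs of neighbouring tags.

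STER_0077 rose furthest, to 2.4 ± 0.06 (SD, n = 2), or 5.29-fold higher (limma adjusted p = 3.42e-10), with 2.47, 2.44 and 2.26 on arrays 1, 2 and 3. Its probe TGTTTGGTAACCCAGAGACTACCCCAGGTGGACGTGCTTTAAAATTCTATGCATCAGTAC, with a GC content of 45%, gave 2.51. It was one of 7 neighbouring tags that rose, with a mean of 1.17 ± 0.03 (SD, n = 2). The run mean was 1.57, 1.15 and 0.82 on arrays 1, 2 and 3, a spread between arrays 1 and 3 that their averaging hides. STER_0919 rose to 2.08 ± 0.13 (SD, n = 2), or 4.22-fold higher (limma adjusted p = 3.12e-09), with 1.68, 2.17 and 2.3 on the 3 arrays. Its probe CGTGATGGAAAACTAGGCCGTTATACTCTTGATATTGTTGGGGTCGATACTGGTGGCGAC gave 2.07, and its run of 5 tags had a mean of 1.37 ± 0.05. The 12 genes that rose furthest lay between 1.33 and 2.4, and 8 of them were in 3 runs.

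**Figure D1:**
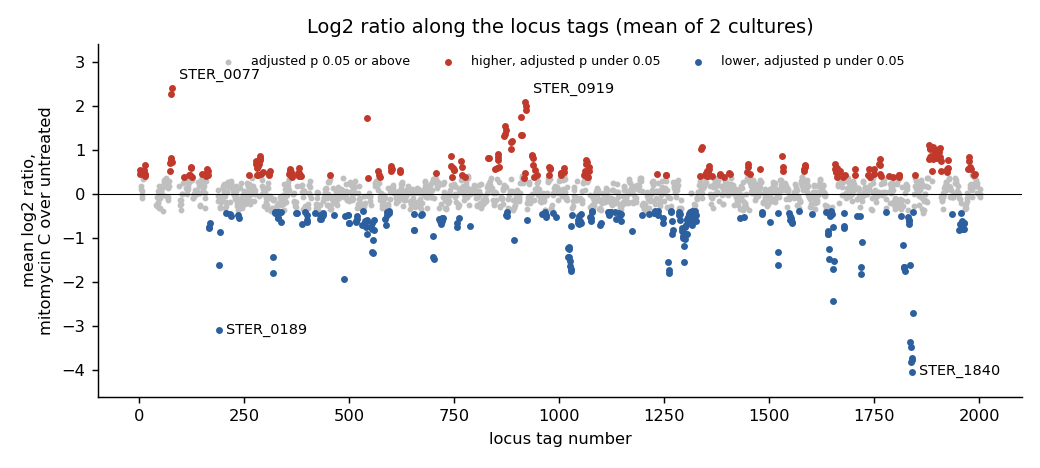
Mean log2 ratio of mitomycin C over untreated (vertical axis) of each of the 1875 numbered tags against its number (horizontal axis), each point being the mean of 2 culture pairs; red and blue points passed the limma test at an adjusted p of 0.05. STER_1840 stands at -4.03 among a column of neighbouring tags that fell, and STER_0077 at 2.4 is the highest point.

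Genes changed in blocks along the tag order. Among the 1875 numbered tags, 45 runs of at least 4 consecutive measured tags changed in one direction, 22 upward and 23 downward. They held 293 tags, or 59.2% of the 495 numbered tags that changed, and 51 of the 73 numbered tags that changed by at least 2-fold. With the tag order shuffled 10000 times the mean number of runs was 1 and the highest 6 (permutation p = 1e-04, the smallest these shuffles can give). Log2 ratios of adjacent tags correlated at 0.8, 0.79 and 0.75 on arrays 1, 2 and 3 (Pearson, across tags, which are not independent replicates). The longest run, 22 tags, rose with a mean of 0.86 ± 0.46 (SD, n = 2) and was unequal between arrays, at 0.82, 1.19 and 0.25. A run of 21 tags fell to -0.77 ± 0.14 and one of 11 tags to -1.31 ± 0.27 (SD, n = 2). These were also unequal between arrays, at -1.32, -0.67 and -0.43 for the 21 tags and -1.91, -1.11 and -1.09 for the 11 tags. The SD between culture pairs does not show such differences between arrays 1 and 3, which were averaged. With a dye term 21 runs were found, with array 3 averaged with array 2 there were 17, and without array 1 there were 25 with 180 tags.

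The second comparison asked whether groups of genes moved together. Genes with a hydrophobic stretch in a translated probe, as membrane proteins and secretion signals have, fell more often than others. Of 235 such genes 72 fell, 14 rose and 149 did not pass the test; adjusted over the list alone, 76 fell and 17 rose. The share that fell was 30.6%, against 11.5% of 1439 genes without such a stretch (odds ratio 3.38, two-sided Fisher's exact p = 1.32e-12, 2.64e-12 after adjustment over both directions), and 6% against 13.9% rose (p = 0.000451). Because neighbours move together, the labels were also shifted along the tag order, and at every position other than the real one at most 57 of these genes fell (two-sided permutation p = 0.0012 over 1674 positions, the smallest they can give). STER_1840 was among these genes. Their mean log2 ratio was -0.26 ± 0.03 (SD, n = 2, limma camera adjusted p = 2.51e-06). With an estimated correlation, which was 0, the camera adjusted p = 0.259. That variant tests on 1 residual degree of freedom and can hardly pass, so it does not decide the question.

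All 6 tags with a letter A or B after the prefix rose, by 0.41 to 1.12 on the log2 scale, and all 6 were above 0 on each array; adjusted over the list alone, 6 rose. Their mean was 0.93 ± 0.18 (SD, n = 2, limma camera adjusted p = 4.74e-06). With an estimated correlation, which was -0.067, the camera adjusted p = 0.259, again on 1 residual degree of freedom. Of the 33 tags with the letter t, 24 had a probe with the conserved T-arm sequence of transfer RNA genes. By limma 0 of these 33 passed, also when adjusted over the list alone, and their mean was 0.13 ± 0.11 (SD, n = 2; camera adjusted p = 0.0564). Of 8 very bright tags with the letter r, 2 rose by limma (3 higher and 2 lower when adjusted over the list alone), with a mean of 0.18 ± 0.53 (SD, n = 2; camera adjusted p = 0.398). Their median was 0.69 and 0.64 on arrays 1 and 2 and -1.11 on the dye-swapped array 3, so the direction of the median followed the dye. Of the 8 tags, 2 kept one sign on all 3 arrays.

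**Figure D2:**
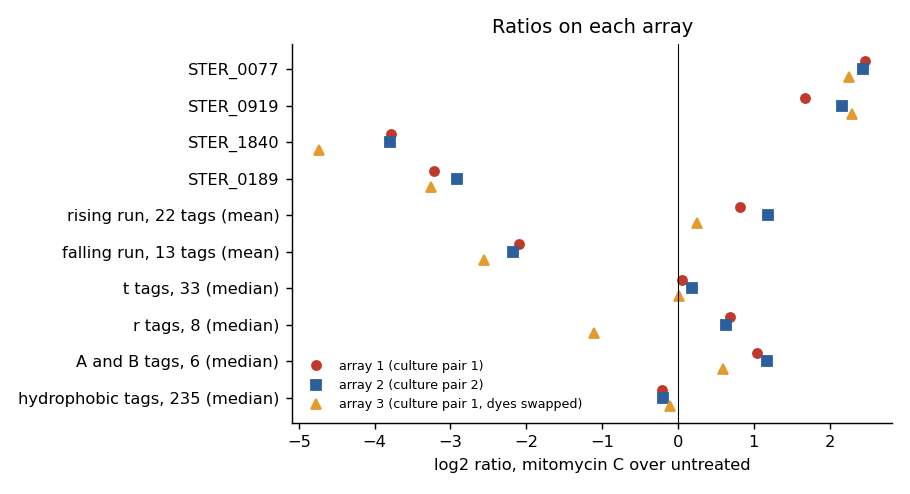
Log2 ratio of mitomycin C over untreated (horizontal axis) on each of the 3 arrays for the 4 named genes, for the longest rising run and the deepest falling run (means over their tags) and for 4 groups of tags (medians). The named genes were chosen among genes with one sign on all 3 arrays, so their agreement in sign is given by the choice. The r tags lie at 0.69 and 0.64 on arrays 1 and 2 and at -1.11 on array 3.

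The third comparison set the arrays against each other. Across 1923 genes the log2 ratios correlated at 0.72 between arrays 1 and 2 (Spearman 0.61), 0.76 between arrays 2 and 3 (0.6) and 0.6 between arrays 1 and 3 (0.46). The bootstrap intervals were 0.68 to 0.76, 0.71 to 0.8 and 0.54 to 0.65. Array 3 was thus closer to array 2 than to array 1, which held the same culture pair according to the labels. The interquartile range of the log2 ratios was 0.67 on array 1, 0.47 on array 2 and 0.38 on array 3. The 2 culture pairs, after averaging of arrays 1 and 3, correlated at 0.83 (Spearman 0.7).

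The fourth comparison asked whether ratios followed distance from the replication origin, as copy number would if replication forks stalled. No map was used here; tag order stood for position and tag 1 for the origin, which is an assumption. On array 1 Spearman rho with distance was -0.39 over 1875 tags, with medians of 0.29 in the nearest of 10 equal parts and -0.31 in the farthest. The planned circular-shift permutation gave p = 0.0267 on array 1, which did not pass after adjustment over 3 arrays (0.0801). Shuffling blocks of 50 tags, a permutation test added later, gave p = 1e-04, the smallest possible (3e-04 after adjustment). On array 2 rho was 0.033 and on array 3 it was 0.059, with adjusted permutation p of 0.435 for both by circular shifts and of 0.58 and 0.5 by blocks. For the mean of the culture pairs rho was -0.115 (circular-shift permutation p = 0.00213; block permutation p = 0.046), and without array 1 it was 0.045, so the trend of the mean rested on array 1.

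**Figure D3:**
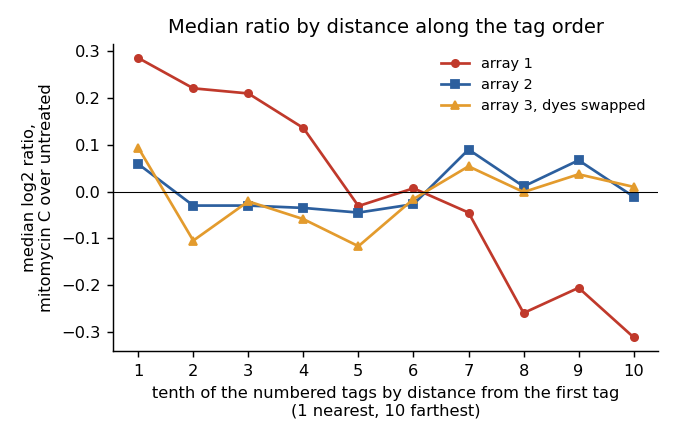
Median log2 ratio of mitomycin C over untreated (vertical axis) in 10 equal parts of the numbered tags by distance from tag 1 along the shorter way round (horizontal axis), with a line for each array. Array 1 goes from 0.29 in the nearest part to -0.31 in the farthest, and the medians of arrays 2 and 3 in those parts lie between -0.01 and 0.09.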

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

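The tests of whether array 3 holds the RNA of array 1, of dye bias and of shared probes were chosen only after the results they address were seen. Control probes of the E1A spike-in type gave a median red signal 1.88-fold above the negative controls on array 1, in data outside the comparisons. The same probes were 1.29-fold to 1.72-fold above them in the other channel and on the other arrays, and in the red channel of array 1 DCP control probes stood at 1.84-fold and bright corner spots at 4.1-fold.

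The ratios of array 1 were lower far from tag 1 (rho -0.39), by the block test and not by the planned test after adjustment, and those of arrays 2 and 3 passed neither. A signal or GC bias of array 1 is argued against: the partial Spearman correlation with distance, holding both, was -0.397. Genomic DNA in 1 labelling would tilt dim genes more than bright ones, yet the slope in the dimmest tags was 0.68 times that in the brightest (interval 0.43 to 1.16). With the position trend removed, array 3 still correlated better with array 2 (0.78) than with array 1 (0.7; difference 0.081, interval 0.035 to 0.135), as it might if it did not hold the RNA of array 1, but arrays 1 and 2, of different culture pairs, correlated at 0.79, so the values do not show that arrays 2 and 3 share RNA, and a dye effect larger on array 1 stays open. A change in gene dosage in 1 culture pair, with another pair on array 3, stays open as an untested hypothesis.

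The longest rising run, 22 mostly very bright tags, rose less on the dye-swapped array (0.25) than on arrays 1 and 2 (0.82 and 1.19). Dye bias as the whole of the rise would put array 3 near -1.01, and the run stood at 0.25 there, with 18 tags above 0. However, 9.2% of stretches of 22 tags on that array were as high. The tags were also called on a mean that includes array 3, so tags low there were less likely to enter the run. The value on array 3 therefore does not settle whether dye bias made the rise. Loess correction at the bright end is argued against, since the run mean was 1.12 with median centring and 0.86 with loess. Whether dye bias shared by bright spots made the rise smaller on array 3 stays open: the dye effect was 0.37 in the run, 0.1 (interval -0.03 to 0.18) in 33 other tags nearest in signal, and 0.93 in the very bright r tags.

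The deepest falling run, 13 tags, held its direction on each array. Of its 57 probes, 3.5% shared 20 bases with a probe of another tag, which argues against cross-hybridisation through sequences that probes share. Only probe sequences were compared, so matches to other parts of genes and near matches were not tested. Dye bias is argued against, with a mean of -2.56 on array 3 and -2.18 on array 2, although the tags were called on a mean that includes array 3. A response to mitomycin C stays open as a hypothesis, on a run found and tested on the same data and in 2 culture pairs. Other differences between the treated and untreated cultures were not tested.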

How the results depend on the processing

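Averaging array 3 with array 2, removal of a smooth trend along the tags and leaving out probes with shared bases were chosen after seeing the data. The 4 named genes kept direction in 72 of 72 alternative values and their call in the 68 with a test (highest adjusted p 6.34e-05). Values, for single probes the most extreme, were 2.31 to 2.56 (STER_0077), 1.92 to 2.23 (STER_0919), -4.48 to -3.8 (STER_1840) and -3.48 to -2.99 (STER_0189). The count of genes changed at least 2-fold stayed within 1.5 times in 16 of 16. The count of all changed genes did so in 12 of 17. It was 264 (112 higher, 152 lower) with a dye term, 285 (114 and 171) with 3 arrays as independent samples, and 225 (94 and 131) with array 3 averaged with array 2, when 44.7% of the 503 genes were kept. Leaving out array 1 or array 3 gave 333 and 269 genes (159 and 128 higher, 174 and 141 lower). The deepest falling run lay between -2.37 and -2.13, and the longest rising run, at 0.86, between 0.54 (without array 2) and 1.12 (median centring). The cause was not tested for any of these.

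The r tags had a mean of 0.57 with median centring (adjusted p = 0.0259), -0.19 with a dye term, and -0.2 to 0.57 with an array left out (0.00302 without array 3). The t tags passed with median centring (0.18, adjusted p = 0.0109), the median over probes (0.13, 0.0329) and the smooth trend removed (0.13, 0.0257), all with the preset correlation; their adjusted p = 0.751 with an estimated correlation. The A and B tags (0.93) and the hydrophobic genes (-0.26) lost their call when camera estimated the correlation (adjusted p = 0.259 for each). The estimates were -0.067 and 0, not above the preset 0.01, so stronger correlation within the groups does not account for the loss. Fry, which tests a group against no change and not against other genes, gave adjusted p = 0.159 for each (0.93 and -0.26). Arrays 2 and 3 correlated at 0.65 with median centring. The distance trend was 0.033 on array 2, 0.059 on array 3, -0.076 without the changed genes (permutation p = 0.662), and -0.239 to 0.045 with an array left out; the cause was not tested.

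A random block for the culture pair gave no value, since its correlation could not be estimated from 3 arrays. Lists matched by symbol and leaving out mobile elements were not run, for lack of gene names. Without array 2, 1 culture pair remains and there is no test. Each ratio sets treated against untreated within a culture pair, so the fit is paired by design. A stricter filter on signal over background removed 3 probes.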

Other observations

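The tests here were chosen after the results were seen. Several falling blocks other than the deepest were of similar size on each array. A run of 5 tags fell to -1.58 ± 0.06 (SD, n = 2), with -1.75, -1.62 and -1.33 on arrays 1, 2 and 3, and a run of 4 tags fell to -1.27 ± 0.02. Another run of 5 tags fell to -1.37 ± 0.09, with -1.11, -1.44 and -1.51. Among rising blocks, a run of 4 tags stood at 1.42 ± 0.1, with 1.09, 1.49 and 1.61 on the 3 arrays. A run of 8 tags rose to 0.5 in the mean of the culture pairs but was at 0.06, 0.45 and 1.03 on arrays 1, 2 and 3.

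Without array 1, 47 of 235 hydrophobic genes and 109 of 1439 others fell (odds ratio 3.05), and with a dye term 38 and 97 (odds ratio 2.67).

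The translated probe of STER_1840 holds the short motif at which prepilin proteins, precursors of surface or DNA-uptake filaments, are cut. A hypothesis is that tags with this motif fell as a set. The motif was found in translated probes of 2 of the 1875 numbered tags. The number of other tags with it that fell was 1, with a log2 ratio of -3.47, and it lay in the same run of 13 tags. With 1 other tag the two-sided Fisher's exact p was 0.14, against 261 of 1873 tags without the motif that fell, so a set of this size cannot decide it. The run may hold genes for such filaments, which needs gene names to test.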
